A study of Oryza sativa with 21 samples.

How the data were processed

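RNA was sequenced from field-grown rice leaves (the second leaf from the top, taken around heading), in 21 libraries from 7 lines with 3 libraries each. The lines were the wild type (WT), the NRP1 overexpression (OE) lines OE-2, OE-3 and OE-4, and the CRISPR/Cas9 lines C-13, C-14 and C-16. The authors deposited 1 table of raw read counts per gene, with 91080 gene identifiers. The submitters' processing notes name FastQC, Trim Galore, STAR 2.5.3a, DESeq2 and the genome build IRGSP-1.0, with no role or order. The read counter, its treatment of strand and its treatment of reads that map to several places are not given in the sources used here, so counts of near-identical paralogs, overlapping genes and antisense genes are uncertain. The deposited counts held whole numbers, and library totals ranged from 13788243 to 19032786. No read was counted in any library for 56267 identifiers.

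The deposited counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Genes were kept by the filterByExpr function with the line as group, which left 21044 genes, and libraries were scaled by TMM. A single model with the 7 lines as groups gave 14 residual degrees of freedom. Each line was compared with WT, and the mean of the 3 lines of a genotype was compared with WT. The error of these contrasts is the spread between libraries, not between lines. OE and CRISPR lines were compared directly after summing counts per line, 3 lines against 3 lines, with 22553 genes passing the filter. Adjusted p-values follow Benjamini and Hochberg with a threshold of 0.05, and "called", "rose" and "fell" refer to it. Standard errors (SE) were computed as the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to a common library size after TMM, given as mean ± SD over 3 libraries of WT or over the means of 3 lines. The labels do not say that the replicates came from separate plants, so p-values measure only the spread between these samples.

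Gene lists for leaf functions and for other tissues were fixed before the data were examined, as were the comparisons, the rule for named genes and most alternative settings. The lists held 190 members in 22 lists. The pairing of gene symbols with locus identifiers in these lists was written from general knowledge. It could not be checked against a reference, since the gene table used here paired only 1 identifier of the count table with an entry. Each symbol therefore stands for the locus printed beside it or held in the list. Among 51 tested loci of 4 photosynthesis lists, 45 lay in the top 5% of genes by abundance. Another 4 planned lists (cytosolic ribosomal, plastid ribosomal, plastid-encoded and mitochondrion-encoded genes) needed gene descriptions and are not analysed here. Lists with at least 5 tested members, 16 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), again with an estimated correlation, and with limma's fry.

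The named genes were NRP1, then up to 10 genes that rose and 10 that fell in each genotype contrast against WT. These had the same sign in all 3 lines, were called in at least 2 of the 3 line contrasts, had a mean of at least 2 CPM in WT or in the lines, and were ranked by the smallest absolute change over the lines. For OE against CRISPR lines the rule took 5 genes each way with non-overlapping line means. Up to 4 members of each list with the smallest adjusted p were added. Since no reference described genes, only list members and at most 2 unnamed identifiers each way were used. Loci whose list symbol is less certain are not discussed singly, except where that doubt is stated beside them. The NRP1 locus was likewise taken from general knowledge. Genes named for other reasons are said to be chosen after their values were seen.

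The procedure was tested on simulated counts with 200 changed genes before use. For OE-2 against WT, simulated over 20722 genes, 80.6% of changes of 1 on the log2 scale were recovered and 16.4% of changes of 0.5. The 3 CRISPR lines against WT gave 82.1% and 32.8%, over the same number of genes. OE against CRISPR lines gave 86.6% and 55.2% over 21033 genes. Unchanged genes made up 5.18%, 4.7% and 5.85% of the calls in these simulations. Simulated lines of a genotype differed only by the spread between libraries, whereas the real OE lines differed from each other in 2066 genes. The shares for OE against CRISPR lines therefore do not describe a comparison of lines that differ. The alternatives were DESeq2 size factors, no filter, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, an added minimum absolute log2 fold change of 1, the replicate block, fewer libraries in the fit, counts summed per line, each line left out and each library left out. Replicate pairs within lines differed by 6.01 to 31 times the Poisson variance, so no pair agreed within sampling noise. Unchanged groups that share the WT libraries were simulated 20 times from the fitted means and dispersions.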

Results

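Transcript counts were obtained for the second leaf from the top of rice plants in the field, in WT, 3 lines overexpressing NRP1 and 3 CRISPR/Cas9 lines edited at NRP1, with 3 libraries per line. The study's title describes NRP1 as a negative regulator of photosynthesis, and the comparisons ask how leaf transcripts differ when it is overexpressed or its gene is edited. Mean total counts per library were 16500000 ± 2300000 in WT (SD, n = 3), 16000000 ± 1600000 in OE (SD, n = 9) and 17100000 ± 1400000 in CRISPR libraries (SD, n = 9). The most abundant gene, the rubisco activase locus RCA (OS11G0707000), took 4.24% to 6.17% of the counts. Principal component 1 held 30.4% of the variance and component 2 held 16.8%. On component 2 the ends were OE-3 replicate 1, at 76.93, and WT replicate 3, at -51.65. The other OE-3 libraries stood at 4.824 and 32.54, and the other WT libraries at -25.62 and -22.

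NRP1 (OS07G0471900) was measured first because it checks the labels. Its locus was taken from general knowledge and stands in no label, so its level in the OE lines supports the locus and the OE labels only together. Its level was 2.46 ± 0.53 CPM in WT, 288 ± 22 in OE-2, 365 ± 29 in OE-3 and 345 ± 30 in OE-4 (SD, n = 3 libraries each). The OE lines thus held 118-fold, 149-fold and 141-fold the WT level, with a mean log2 fold change of 7.08 (SE 0.16, edgeR adjusted p = 1.19e-16). In the CRISPR lines NRP1 was at 3.13 ± 0.75 CPM in C-13, 2.18 ± 0.15 in C-14 and 3.3 ± 0.25 in C-16. The mean of the CRISPR lines was 1.16-fold that of WT (edgeR adjusted p = 0.37), so counts did not separate CRISPR from WT. An edit need not lower the transcript, so this level says nothing of the CRISPR labels.

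**Figure D1:**
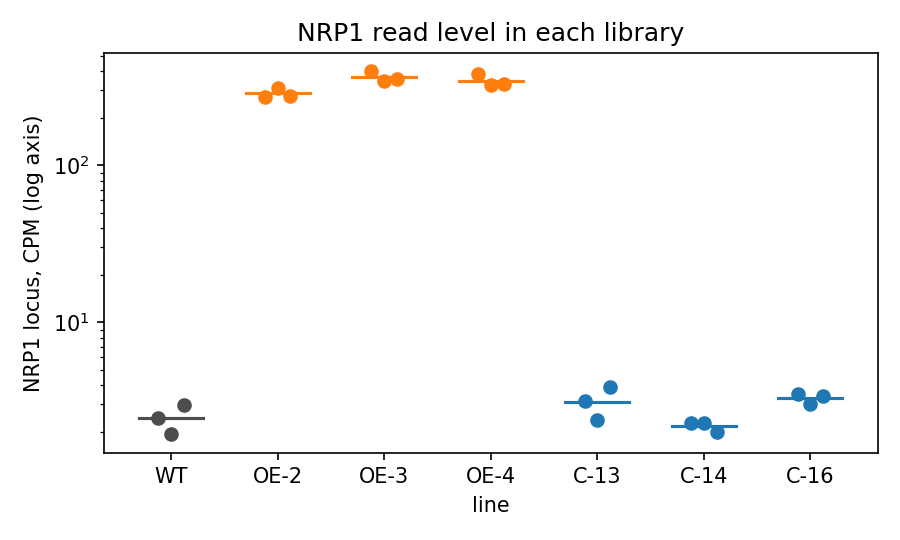
NRP1 level in CPM (vertical log axis) in each of the 21 libraries by line (horizontal axis), with points for libraries and bars for line means. OE means lie between 288 and 365 CPM, and WT and CRISPR means between 2.18 and 3.3 CPM.

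The first comparison asked what overexpression changed against WT. GS1;2 (OS03G0223400), a cytosolic glutamine synthetase of nitrogen assimilation, fell from 146 ± 15 CPM in WT to 94.8 ± 15 in the OE lines (log2 fold change -0.63, SE 0.11, edgeR adjusted p = 0.0024). The Calvin-Benson cycle enzyme gene PRK (OS02G0698000) fell to 0.767-fold, SSI (OS06G0160700, a starch synthase) to 0.648-fold and HEMA1 (OS10G0502400, an early step of chlorophyll synthesis) to 0.67-fold. Hd3a (OS06G0157700), which encodes the florigen, fell to 0.793-fold. SPX2 (OS02G0202200), a gene of the phosphate starvation list, rose 2.31-fold from a low level, 1.2 ± 0.26 CPM in WT. Its estimate in CRISPR lines was also up, at 1.8-fold (edgeR adjusted p = 0.0967). OE and CRISPR lines did not differ in it (edgeR adjusted p = 0.148). The calls for HEMA1 and SPX2 ended when any 1 of the 3 WT libraries was left out. Those for PRK, SSI and Hd3a ended without 2 of the 3, and GS1;2 was called without each in turn. With the replicate number as a block, HEMA1 and SSI were not called (edgeR adjusted p = 0.0556 and 0.0583).

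The photosynthesis genes had median log2 fold changes of -0.01 in OE-2 (2 loci higher, 1 lower), 0.34 in OE-3 (11 higher, 1 lower) and -0.25 in OE-4 (0 called). In a test chosen after the data were seen, 35 of 51 loci were higher in OE-3 than in OE-4 and 0 lower, with 12 higher without OE-3 replicate 1 and 22 and 21 without OE-4 replicates 1 and 2. Among the 51 loci for the antenna, photosystems, electron carriers and Calvin-Benson cycle, 2 rose and 1 fell in the mean of the lines, with a median of 1.01-fold. The 2 that rose were OS02G0103800 and OS12G0291400, listed as LFNR2 and RBCS5, at 8.96 and 16.4 CPM in WT. These levels are low for such genes and put the symbols in doubt, although counts of near-identical paralogs are uncertain too. Some loci that did not rise here were also low in WT. Examples are those listed as LFNR1 (OS06G0107700, 0.765 CPM), PsbY (OS08G0119800, 21.8) and Lhcb6 (OS04G0457000, 70.3), the last of which rose in CRISPR lines. None of the 16 tested lists was called in the OE lines by camera, by camera with an estimated correlation or by fry (lowest fry adjusted p = 0.368). Without line OE-3 camera called the antenna and photosystem lists lower, and without line OE-4 it called electron carriers higher. For the antenna the adjusted p was 0.892, with 0 of 13 members called. Photosystem subunits had an adjusted p of 0.945, with 0 of 16 called. Electron carriers gave 0.228 with 1 of 7 higher, and Calvin-Benson genes 0.892 with 1 of 15 higher and 1 lower. The corresponding adjusted p was 0.923 for chlorophyll biosynthesis, 0.624 for photorespiration, 0.948 for chlorophyll breakdown, 0.898 for nitrogen assimilation and for abscisic acid response, and 0.892 for jasmonate. It was 0.54 for sucrose and starch, circadian clock, flowering time, light signalling, defence and phytoalexins. Adjusted over the list alone, 3 sucrose and starch members and 3 flowering members were lower.

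In all, 983 of 21044 genes were called in the OE lines, 312 higher and 671 lower, by edgeR's quasi-likelihood test. The lines differed in number: 429 genes in OE-2 (154 higher, 275 lower), 3971 in OE-3 (1644 higher, 2327 lower) and 122 in OE-4 (89 higher, 33 lower). Changes in all 3 OE lines in the same direction were found for 45 genes (32 higher, 13 lower). Independent lists would share 0.0509 and 0.0477 genes, and simulated unchanged lines sharing the WT libraries gave 0 in each of 20 simulations. Independent lists ignore the shared WT libraries, and simulated genes were independent and unchanged, so few calls were possible. Neither reference tells a shared change from a deviation of the WT libraries. Unnamed loci called in the OE lines included OS03G0115800, at 0.469 ± 0.063 CPM in WT and 203 ± 27 in OE lines. Another, OS03G0621700, fell from 18 ± 6.3 to 2.03 ± 0.66 CPM. With lines as replicates and WT as 1 sample, assumed to vary like the lines, 16 genes were called. In the model of all lines 182 were called without WT replicate 3, 278 without WT replicate 2, 1658 without OE-3 replicate 2, and 630 and 655 without OE-4 replicates 1 and 2. With only the 6 libraries compared, OE-3 had 161 calls. In the model of all lines it had 1567 without its replicate 1 and 1876 without WT replicate 3. OE-2 had 163, 256 and 192 without its own replicates 1, 2 and 3, 189 and 166 without WT replicates 2 and 3, and 1067 and 647 without OE-3 replicates 1 and 2.

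**Figure D2:**
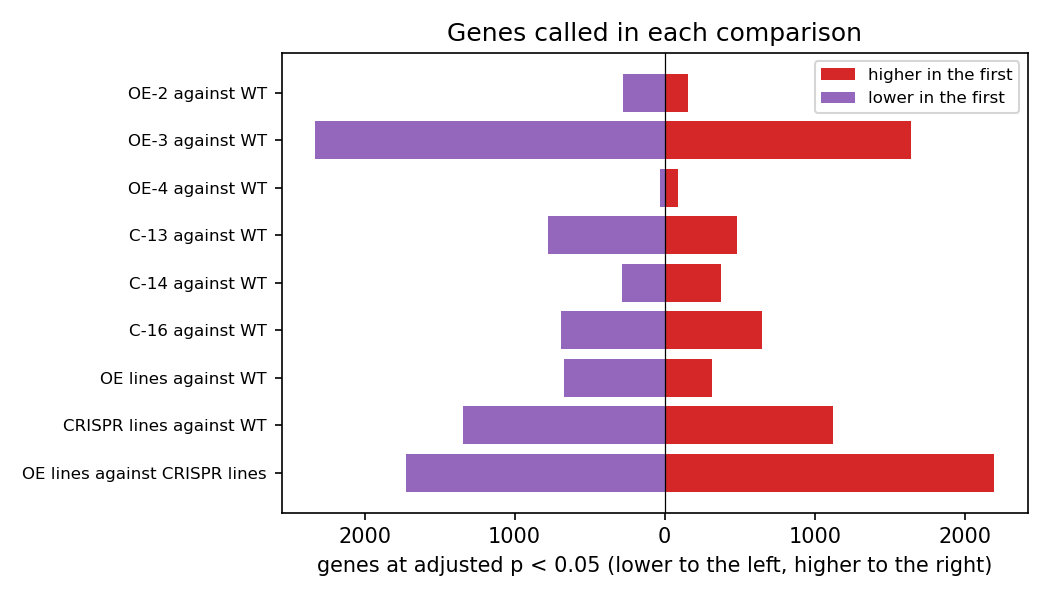
Number of genes at the edgeR threshold in each comparison, lower to the left and higher to the right on the horizontal axis, for the 9 comparisons on the vertical axis. OE-3 reaches 2327 lower genes and OE-4 33.

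The second comparison asked what the CRISPR lines changed against WT. Photosynthesis genes were higher in them: 31 of the 51 loci rose and 0 fell, with 49 of 51 estimates above WT and a median of 1.35-fold. The pooling of the 4 lists was chosen after the data were seen. Antenna genes bind the chlorophyll that harvests light, and 8 of 13 rose (median log2 fold change 0.43, camera adjusted p = 1.5e-06; adjusted p = 0.251 with an estimated correlation). Lhcb4 (OS07G0558400) rose from 2010 ± 410 CPM to 3390 ± 280 (log2 fold change 0.75, SE 0.15, edgeR adjusted p = 0.00411). Of the photosystem subunits, 12 of 16 rose (median 0.44, camera adjusted p = 7.97e-07; adjusted p = 0.251 with an estimated correlation), among them PsbQ (OS07G0544800) at 1.57-fold and PsaE (OS07G0435300) at 1.38-fold.

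Electron carriers and ATP synthase subunits rose for 4 of 7 members (median 0.47, camera adjusted p = 0.000611; adjusted p = 0.145 with an estimated correlation), with PetC (OS07G0556200) at 1.39-fold. Calvin-Benson genes rose for 7 of 15 (median 0.32, camera adjusted p = 1.49e-05; adjusted p = 0.145 with an estimated correlation), with GAPB (OS03G0129300) at 1.42-fold. Chlorophyll biosynthesis genes rose for 4 of 12 (median 0.40, camera adjusted p = 0.000362; adjusted p = 0.322 with an estimated correlation), with DVR (OS03G0351200) at 1.48-fold and PORB (OS10G0496900) at 1.67-fold. Light signalling genes rose for 2 of 10 (median 0.33, camera adjusted p = 0.00178; adjusted p = 0.119 with an estimated correlation). These were CGA1 (OS02G0220400) at 1.42-fold and PIL15 (OS01G0286100) at 1.52-fold. Adjusted over the list alone, 10 antenna, 15 photosystem, 4 electron carrier, 11 Calvin-Benson, 6 chlorophyll biosynthesis and 5 light signalling genes were higher, and 1 photosystem gene, PsbR (OS07G0147500), was lower (log2 fold change -1.20). The fry test, which asks whether a list moves one way and does not compare it with other genes, gave an adjusted p of 0.00533 for antenna and photosystem lists, 0.00105 for electron carriers and the Calvin-Benson cycle, 0.0196 for chlorophyll biosynthesis and 0.000257 for light signalling.

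Defence genes were lower for 4 of 9 members (median -1.52, camera adjusted p = 0.000113; adjusted p = 0.145 with an estimated correlation), and for 8 when adjusted over the list alone (fry adjusted p = 0.00179). The 4 called members, PAL, PR10b, NH1 and PBZ1 (OS12G0555500), had negative estimates in each CRISPR line. The list median was -2.58 in C-13 (7 called), -0.54 in C-14 (1 called) and -0.62 in C-16 (3 called). In C-13 WRKY45 (OS05G0322900), WRKY62 (OS09G0417800) and WRKY76 (OS09G0417600) were at -2.58, -4.11 and -4.58. They were at -1.83, -3.18 and -2.7 in OE-2, uncalled, at -0.0543, -0.467 and 0.0695 in C-14 and at -0.481, -0.62 and -0.284 in C-16. In WT they varied widely, at 94.3 ± 78, 11.3 ± 12 and 35.7 ± 23 CPM. None was called in the mean of the CRISPR lines (edgeR adjusted p = 0.108, 0.0526 and 0.0677). These WRKY genes and PsbR were chosen after their values were seen. PAL (OS02G0627100), which opens the phenylpropanoid pathway, was at 102 ± 77 CPM in WT and 14.4 ± 3.8 in the CRISPR lines (log2 fold change -2.86, SE 0.41, edgeR adjusted p = 0.00023; -2.06 without WT replicate 1). PR10b (OS12G0555000) fell to 0.348-fold and NH1 (OS01G0194300), a regulator of salicylic acid responses, to 0.583-fold. LOX8 (OS08G0508800), a lipoxygenase, fell to 0.237-fold and CAD2 (OS02G0187800), of lignin synthesis, to 0.264-fold. The other tested member of its secondary cell wall list, CESA4 (OS01G0750300), went the other way, from 0.304 ± 0.19 to 1.03 ± 0.28 CPM (3.18-fold, edgeR adjusted p = 0.0184), and was not called without WT replicate 1 or 3. The senescence regulator gene NAP (OS03G0327800) fell to 0.653-fold. Hd3a rose 1.3-fold. GS1;2 rose 1.52-fold, while GS1;1 (OS02G0735200) fell to 0.72-fold.

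Other lists were not called in the CRISPR lines. Camera's adjusted p was 0.744 for photorespiration, 0.0507 for chlorophyll breakdown (2 of 7 lower; fry adjusted p = 0.0366), 0.484 for sucrose and starch, and 0.414 for the circadian clock. It was 0.277 for nitrogen assimilation (1 higher, 3 lower) and for phytoalexins, 0.332 for flowering and for abscisic acid response, and 0.383 for jasmonate, whose median (0.35) and test (lower) differed in sign. Lists too small to test held HSFA2d (OS03G0161900, a heat stress factor) at 1.27-fold and SLAC1 (OS04G0574700, a guard cell anion channel) at 1.31-fold, both called. The SLAC1 call ended when any 1 WT library was left out, and the HSFA2d call held in only 1 of those 3 fits. Markers of cell division had 0 tested members, and those of panicle, anther and seed had 2, of which OS03G0215400, listed as MADS1, rose 1.41-fold from 16.8 ± 1.2 CPM. That level in leaf puts the symbol in doubt, so this rise is no measure of panicle tissue.

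The CRISPR lines had 2464 called genes by edgeR, 1123 higher and 1341 lower. C-13 had 1262 (483 higher, 779 lower), C-14 had 666 (378 higher, 288 lower) and C-16 had 1342 (650 higher, 692 lower). In all 3 CRISPR lines 326 genes changed in the same direction (155 higher, 171 lower). Independent lists would share 0.268 and 0.351, and 20 simulations of unchanged lines gave 0. As for the OE lines, neither reference tells a shared change from a deviation of the WT libraries. Without WT replicate 1 the counts were 668 for the genotype, 83 for all 3 lines and 3 for the photosynthesis loci, and without WT replicate 3 the last was 7. With lines as replicates and WT as 1 sample, assumed to vary like the lines, edgeR called 306 genes and 0 of the photosynthesis loci, of which 7 had an unadjusted value under the threshold (6 higher). The median of these loci was then 0.38, with 49 of 51 positive. With the replicate block 26 of these loci were called higher, and without line C-16 the numbers were 1633 and 8. Of the genes named above, Lhcb4, GAPB, PetC, DVR, GS1;2, PAL, PR10b, NH1, LOX8, CAD2, NAP and OS03G0215400 were called without each WT library in turn. Without WT replicate 1, C-13, C-14 and C-16 had 222, 221 and 331 genes. C-13 had 485, 762 and 451 without its own replicates 1, 2 and 3, C-14 had 211 without its replicate 1 and 1024 without OE-3 replicate 1, and C-16 had 486 and 335 without its replicates 1 and 3. The number alike in all 3 lines was 176 and 180 without C-13 replicates 1 and 3, 117 without C-14 replicate 1, and 198 and 153 without C-16 replicates 1 and 3. The camera test called at least 7 lists in 14 of 100 random groupings of these libraries, the real one included, so the list calls do not stand apart from chance groupings.

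**Figure D3:**
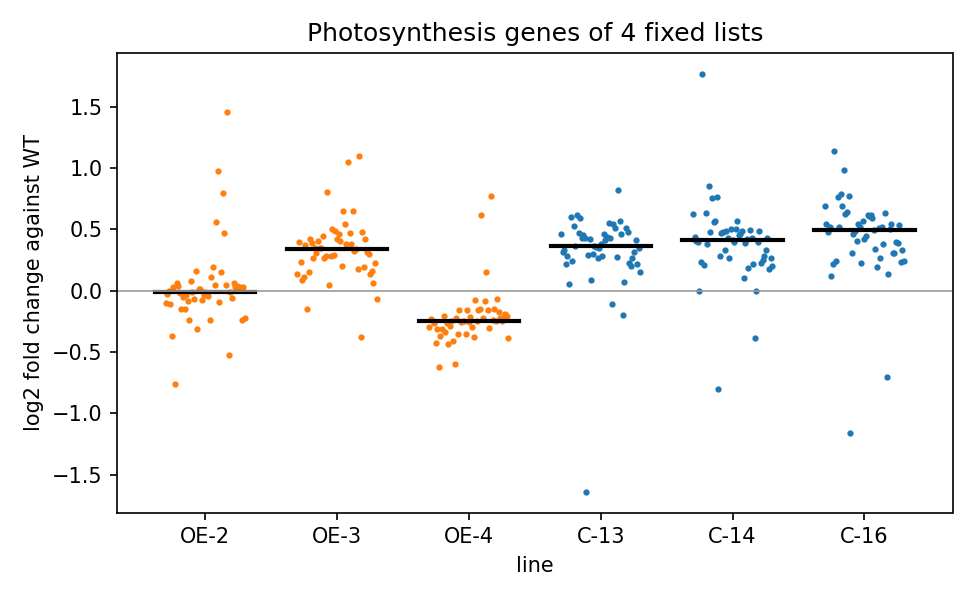
Log2 fold change against WT (vertical axis) of the 51 photosynthesis loci in each line (horizontal axis), with points for loci and black bars for medians. Medians are 0.36, 0.41 and 0.50 in C-13, C-14 and C-16, and -0.01, 0.34 and -0.25 in OE-2, OE-3 and OE-4.

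The third comparison set OE lines directly against CRISPR lines, with each line as 1 replicate. Photosynthesis loci were lower in OE lines for 11 of 51 and higher for 2, with 46 estimates below 0 and a median of 0.803-fold. Lhcb4 was 0.585-fold in OE lines relative to CRISPR lines (edgeR adjusted p = 0.0167) and Lhca1 (OS06G0320500) 0.644-fold. Chlorophyll biosynthesis genes were lower for 6 of 12, including PORB at 0.577-fold and HEMA1 at 0.517-fold, and higher for 1. Of the chlorophyll breakdown genes, 4 of 7 were higher, including NAP at 1.58-fold and RCCR1 (OS10G0389200) at 1.73-fold.

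PAL was 6.91-fold higher in OE lines than in CRISPR lines (log2 difference 2.79, SE 0.25, edgeR adjusted p = 0.000855), at 96.7 ± 28 CPM in the OE lines. In this paragraph CPM values are from the counts summed per line, with the SD over the 3 lines. CAD2 was 4.5-fold higher, PR10b 3.03-fold higher and ASN1 (OS03G0291500, an asparagine synthetase) 4.44-fold higher. HSFA2a (OS03G0745000), also taken by the rule, was 5.5-fold higher, at 2.14 CPM in OE lines. The 5 lower genes taken were SalT (OS01G0348900, 0.0638-fold), PORA (OS04G0678700, 0.264-fold), FKF1 (OS11G0547000, 0.286-fold), Lhcb1.2 (OS01G0720500, 0.31-fold) and CESA4 (0.311-fold). In OE lines SalT, FKF1 and CESA4 were at only 0.077, 0.283 and 0.313 CPM. GS1;2 was 0.439-fold (edgeR adjusted p = 0.00213) and Hd3a 0.618-fold. The list tests used single libraries of the model of all lines, so their error is that between libraries. Camera called 5 lists: antenna (adjusted p = 1.49e-05), photosystem subunits (3.66e-05), Calvin-Benson cycle (0.000748) and chlorophyll biosynthesis (0.00464) were lower, and defence (0.0133) was higher. With an estimated correlation camera called none, with adjusted p = 0.435 for antenna, Calvin-Benson cycle and defence and adjusted p = 0.487 for photosystem subunits and chlorophyll biosynthesis. Fry called these 5 and further lists, with adjusted p = 0.000206 for antenna, 0.000505 for photosystem subunits, 0.00011 for the Calvin-Benson cycle, 0.00114 for chlorophyll biosynthesis and 0.000611 for defence. With lines as replicates, a test added after the data were seen, camera called the same 5 lists, with adjusted p = 0.000529 for antenna, 0.00584 for photosystem subunits and chlorophyll biosynthesis, 0.0117 for the Calvin-Benson cycle and 0.0291 for defence. It called 0 with an estimated correlation (lowest adjusted p = 0.631), and fry called none of these 5 (adjusted p from 0.0604 to 0.224). Fry called 3 others, chlorophyll breakdown (higher) and nitrogen assimilation (higher) with adjusted p = 0.00341 each and flowering (lower) with 0.022.

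By edgeR, 3916 of 22553 genes differed, 2191 higher and 1725 lower in OE lines, and single libraries gave 8910. The photosynthesis count was 24 without OE-3 replicate 1, 4 without OE-3 replicate 2, and 7 without C-14 replicate 3. It was 1 without each of the lines OE-2, C-14 and C-16, 4 without C-13 and 36 without OE-3. All differing genes numbered 2211, 1719, 2108 and 1545 without OE-2, C-13, C-14 and C-16, and camera called 2 lists without OE-4. For 3830 of the differing genes that were also tested against WT, the WT mean lay between the OE and CRISPR means for 79.8%. It was nearer to the OE mean for 68.5%. No chance share was computed, and no WT library was left out here, so these shares may rest on 1 library. On component 1, WT replicate 1 (-27.08) lay among the OE libraries (-52.21 to -21.54), and WT replicates 2 and 3 stood at -2.307 and 2.926. Without WT replicate 1, 1273 genes were called in OE and 668 in CRISPR lines against WT.

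The last comparison asked whether OE and CRISPR lines moved genes in opposite directions from WT. GS1;2 and Hd3a were among 23 genes that fell in OE and rose in CRISPR lines, and 4 genes did the reverse. A larger number, 159, changed in the same direction in both (70 higher, 89 lower). OS03G0115800 was among them, at 123 ± 28 CPM in CRISPR lines. Independent lists would share 16.6 genes higher and 42.8 lower in both. They would share 35.8 that fell in OE and rose in CRISPR lines, and 19.9 of the reverse. Both opposite counts, 23 and 4, thus lay below those of independent lists, which ignore the shared WT libraries. Across genes, which are not independent replicates, the log2 fold changes of both contrasts had r = 0.423 and a covariance of 0.12. Simulated unchanged groups sharing the WT libraries gave a mean r of 0.747 and a covariance of 0.0427, with 0 genes called in both. No simulated gene was changed, so that 0 says nothing of a shared deviation of WT. WT has too few libraries to be split, so part of the excess in covariance may come from the shared WT libraries. Without WT replicate 3 the counts were 67 in the same and 4 in opposite directions. Without WT replicate 2 they were 84 and 4, and without WT replicate 1 the opposite count was 14. That count was 17 and 14 without OE-2 replicates 1 and 3, 16 and 13 without OE-4 replicates 1 and 2, 17 without C-13 replicate 1 and 15 without C-16 replicate 3. The same-direction count was 296 and 275 without OE-3 replicates 1 and 2.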

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

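The tests on single libraries and on the spread of OE-3 were chosen after the result was seen, as were the pooling of the photosynthesis loci and the test of NRP1 between OE lines.

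The 3 OE lines differed from each other in 2066 genes, and the 3 CRISPR lines in 93, by edgeR's test across the lines of a genotype. Most calls among OE lines separated OE-3 from OE-4, with 3032 genes. OE-3 had 3971 calls against WT. In a fit without its replicate 1 it had 1567, OE-2 1067 and OE-4 129, so that library cannot be told apart from a difference of the line, as the lead over OE-2 is too small to decide. When only the 6 libraries compared set the error, OE-3 had 161 calls and OE-2 285, which is consistent with a spread among OE-3 libraries wider than the pooled error; the median SD of log2 CPM was 0.232 in OE-3, 0.225 in WT, 0.176 in OE-2 and 0.148 in OE-4. A higher NRP1 level stays open: NRP1 in OE-3 exceeded that in OE-2 by 0.34 on the log2 scale (edgeR adjusted p = 0.193) and that in OE-4 by 0.08 (edgeR adjusted p = 0.678), and without adjustment the 2 edgeR tests gave 0.00882 and 0.49. NRP1 in OE-4 also exceeded that in OE-2, by 0.26 (edgeR adjusted p = 0.303), although OE-4 had 122 calls and OE-2 429.

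The photosynthesis loci were higher in CRISPR lines than in WT by a median log2 fold change of 0.43, with 31 of 51 called. A difference in scaling would move other abundant genes too, but 974 abundant genes outside the lists had a median of 0.0797 (bootstrap interval 0.0634 to 0.0998), well under it. Abundant genes still leaned upward, with 152 called higher and 55 lower, against a median of 0.00825 over all genes. The TMM factors also differed, at 1.03 ± 0.025 in WT (SD, n = 3) and 0.955 ± 0.02 in CRISPR libraries (SD, n = 9). This difference raises CRISPR values against WT for every gene. The bootstrap resamples genes, so its interval does not measure the spread between libraries. A single WT library was not the whole cause of the size, since the lowest median without 1 WT library was 0.34, although the number of calls depended on WT replicates 1 and 3. Of 100 groupings of the 12 libraries, only the real one gave as many higher loci (24 in a fit of these libraries, highest other 0). These groupings also break up the lines, so they do not test differences between lines, and with lines as replicates against 1 WT sample 0 loci were called, while the median was 0.38 with 49 of 51 positive. An effect of the genotype remains a hypothesis, as an untested difference between the WT and edited plants in growth or background is not excluded.

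For genes changed the same way in OE and CRISPR lines, the covariance of 0.12 exceeded the simulated 0.0427, but simulated genes are independent, so chance values shared through WT cannot be told apart from a shared effect. Of 152 such loci with a chromosomal locus number, 21.7% had another member within 10 tested loci, against a median of 13.2% in 10000 random sets, the central 95% of which ended at 21.1%. This is just past the bound, as segments of another background in WT, or neighbouring genes that respond together, would give. The largest cluster held 4 loci. The loci were spread over all chromosomes, from 8 on chromosome 9 to 20 on chromosome 1. Only the real grouping among 60 of the 21 libraries gave 159 same-direction genes (highest other 4) or 27 opposite ones (highest other 0). The other groupings mix lines within a group, which widens the error and lowers the counts. They therefore do not tell a shared effect from a deviation of the WT libraries. Effects of transformation were not tested, since no vector control was analysed here.

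Random regroupings of the libraries were also examined for the other counts. Where they mix lines within a group, the error widens, so they do not tell a change of the genotype from a deviation of WT. For OE lines, 3 of 100 groupings gave at least the real 315 genes, and the highest other gave 2088, with 2 OE-3 libraries and 1 OE-2 library in the place of WT, and the next 715, with the 3 OE-3 libraries there, which points to a structure among the OE libraries. For CRISPR lines 1 of 100 gave the real 2134 (highest other 17). Genes alike in all 3 lines numbered 40 for OE (highest other 2) and 272 for CRISPR (highest other 8), in 1 of 100 each. The list test gave 0 lists in OE (highest other 8), which every grouping reaches, so that share decides nothing. It gave 7 in CRISPR, which 14 of 100 reached (highest other 9). The single lines and the OE against CRISPR comparison have 10 splits, too few for a share under 0.05. Real counts were 285, 161, 91, 764, 137 and 388 for OE-2, OE-3, OE-4, C-13, C-14 and C-16, and 3916 for OE against CRISPR, with 0 as the highest other and 1 split as large in each. For the lists between OE and CRISPR, 3 of 10 splits gave at least 5 lists (highest other 8).

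The mean log2 CPM of the phytoalexin list was 1.91 in C-16 replicate 2, apart from the next CRISPR library at 0.96. The mean log2 CPM of the abscisic acid list was 4.06 in OE-2 replicate 1, apart from the next OE library at 3.57. These were 2 of 40 groups of libraries examined, and chance alone sets apart about 5% of groups.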

How the results depend on the processing

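The pooled photosynthesis counts, the same-direction count, the named genes without each WT library, the unadjusted count and the list tests with lines as replicates, the libraries of other lines left out and the pairs of OE lines were added after the data were seen. NRP1 kept its direction and its side of the threshold in every line under the settings in which it was scored. It was not scored with the minimum change, fewer libraries in the fit, counts summed per line or a line left out. With DESeq2 size factors no count moved by over 1.5 times. The cause of the following moves was not tested, except that the minimum change can only lower a count.

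With an absolute log2 fold change of at least 1 the counts were 259 (OE-2), 972 (OE-3), 655 (C-13), 369 (C-14), 636 (C-16), 318 (OE lines), 808 (CRISPR lines), 180 (all 3 CRISPR lines), 5 (opposite), 75 (same direction), 1116 (OE against CRISPR), 0 photosynthesis loci higher in CRISPR lines and 1 lower in OE than in CRISPR lines. With no filter they were 668 (OE-2), 1038 (C-14), 543 (all 3 CRISPR lines) and 41 (opposite). With a mean of at least 5 CPM they were 249 (OE-2), 49 (OE-4), 409 (C-14), 24 (all 3 OE lines), 207 (all 3 CRISPR lines) and 95 (same direction). The DESeq2 Wald test gave 885 (OE-2), 1229 (C-14), 1528 (OE lines), 569 (all 3 CRISPR lines), 60 (opposite), 239 (same direction) and 24 photosynthesis loci lower in OE than in CRISPR lines. Only the 6 libraries compared gave 285 (OE-2), 161 (OE-3), 764 (C-13), 137 (C-14) and 388 (C-16), and only the 12 gave 315 for OE lines. Counts summed per line gave 16 (OE lines), 306 (CRISPR lines) and 0 photosynthesis loci. Single libraries gave 8910 between OE and CRISPR lines, with 41 photosynthesis loci lower. An estimated correlation left 0 lists in CRISPR lines and 0 between OE and CRISPR lines.

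Leaving out line OE-2 gave 444 (OE lines), 2211 (OE against CRISPR) and 1 photosynthesis locus lower. Without line OE-3 there were 259 in OE lines, 36 photosynthesis loci lower than in CRISPR lines and 2 lists called in OE lines, where the photosystem list turned lower (median -0.16). Without line OE-4 there were 2220 in OE lines, 1 list in OE lines and 2 lists between OE and CRISPR. Without C-13, C-14 and C-16 in turn, OE against CRISPR gave 1719, 2108 and 1545 genes and 4, 1 and 1 photosynthesis loci lower; without C-16, CRISPR lines had 1633 genes and 8 photosynthesis loci higher.

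Leaving out 1 library of the lines compared at a time gave 163 to 547 (OE-2), 1567 to 4562 (OE-3), 86 to 126 (OE-4), 222 to 1298 (C-13), 211 to 747 (C-14), 331 to 1201 (C-16), 182 to 1658 (OE lines), 668 to 2907 (CRISPR lines), 37 to 57 (all 3 OE lines), 83 to 402 (all 3 CRISPR lines), 4 to 36 (opposite), 67 to 296 (same direction), 3 to 34 photosynthesis loci higher in CRISPR lines and 4 to 24 lower in OE than in CRISPR lines. Libraries of other lines also moved counts, with OE-2 at 1067 and 647 without OE-3 replicates 1 and 2 and C-14 at 1024 without OE-3 replicate 1. Of 59 gene calls in CRISPR lines, 18, 55 and 25 held without WT replicates 1, 2 and 3, and of 12 in OE lines 9, 5 and 5.

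Replicate numbers are shared across lines, but same-numbered libraries did not deviate together (mean r = 0.00915; 4 of 18 pairs with WT over 0.1; 7 of 21 libraries closest to their own number). With the replicate block, the calls of HEMA1 and SSI in OE lines and of PsaD, PsaK, PsaL, cpFBP and SBP in CRISPR lines ended, with adjusted p from 0.0516 to 0.0628, and 26 photosynthesis loci were higher in CRISPR lines. OE lines had 1051 genes, CRISPR lines 2424, and the single-library comparison of OE and CRISPR lines 8870.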

Other observations

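Some regulators of chloroplast development and light signalling differed between OE and CRISPR lines. GLK1 (OS06G0348800) was 0.653-fold in OE lines relative to CRISPR lines (edgeR adjusted p = 0.0212), PIL13 (OS03G0782500) 0.693-fold and CGA1 0.705-fold, while PHYA (OS03G0719800), a phytochrome gene, was 1.3-fold. In this list 4 of 10 members were lower and 1 higher, and camera did not call it (adjusted p = 0.0997). Nitrogen genes moved both ways, with GS1;1 1.75-fold and ASN1 4.44-fold higher and GS1;2 0.439-fold. With single libraries the list had an adjusted p of 0.331 by camera and 0.158 by fry. With lines as replicates it was 0.218 by camera, 0.631 by camera with an estimated correlation and 0.00341 by fry, so only the last called it. GLK1, PIL13 and PHYA were chosen after their values were seen.

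The photosynthesis loci were compared line by line after the data were seen. In OE-3, 11 of 51 loci were higher and 1 lower than in WT, with a median log2 fold change of 0.34, whereas in OE-4 none was called and the median was -0.25. In C-16, 24 of the loci were higher, in C-14 7 and in C-13 4, and 0 were lower in each.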
